A study of Homo sapiens with 4 samples.

How the data were processed

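Exosomal small RNA of Hep3B cells was measured on 4 microarrays, 2 from cells given 10 µM camptothecin for 2 days and 2 from untreated cells. Per the labels' protocols, exosomes were isolated from conditioned medium with a commercial kit, small RNA was extracted with a miRNA kit and checked for integrity, and the RNA was reverse-transcribed, amplified and coupled to the dye Cy5. The scanner, its software, the background correction and the normalization are not given in the sources used here. Per the labels, a sample's group is its treatment, and its replicate number is that in its title.

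The deposited values of each array are intensities on a linear scale, in arbitrary units, 1 per probe. What had been done to them was read from the values. The 2 arrays of a group hold the same 1308 sorted values, which is what quantile normalization within each group gives, and all 4 arrays share the 75th percentile of 250.15. Low values are whole multiples of a step, 0.585 on treated and 0.427 on untreated arrays, for 88.8% and 92.4% of entries within 0.01 of a step. Read as averages of whole scanner values multiplied by a factor per group, these steps give factors of 1.17 for treated and 0.854 for untreated arrays, a ratio of 0.45 on the log2 scale. On that reading the unscaled lowest values were 93 and 107, the medians 145.5 and 185.25, the 75th percentiles 213.75 and 292.75 and the highest values 7208 and 15211, treated first. If read rightly, these steps bear on the measurements in 2 ways. Quantile normalization within groups shrinks the spread between replicates, so p-values are too small. A larger factor for the treated group, if the signal still holds background, could lift its dim probes against those of the untreated group. On this reading the lowest values went from 93 against 107 to 108.8 against 91.4 as deposited, treated first. The share of background in each probe, and so the size of any such lift, is not known.

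The authors' second table gives log2 ratios of each treated over each control array, per the file headers. These log2 ratios equal the differences of the deposited intensities on the log2 scale within 5e-10, so that table holds the same values and was used only for this check and for the names of the probes. Its headers call the comparator DMSO, while the labels say no treatment, and which is right was left open. Another 4 columns of values per array in that table were not used. Probes were named from that table. 12 probes carry the names of several miRNAs and were kept under the joint name. Names are those of the array's design, in which miR-210, miR-1 and others lack an arm. No genome build is given, so no positions are printed.

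Values were taken as log2 of the deposited intensity with no further normalization and no pseudocount. The 1308 entries were compared between groups with lmFit and eBayes (intensity trend) of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all entries and a threshold of 0.05. Fold changes are treated over untreated, and their errors are limma's standard errors. No probe is marked as detected or not and no background reading was used here, so the height of dim probes over background is unknown.

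The miRNAs named in the text follow a rule fixed before the data were examined. It takes, among entries past the test whose 2 treated arrays both lie on 1 side of both untreated arrays and whose higher group mean is at or above the median level, the 12 highest and 12 lowest by log2 fold change. It adds let-7a-5p, miR-16-5p, miR-21-5p, miR-34a-5p, miR-122-5p, miR-192-5p, miR-210, miR-221-3p, up to 4 members past the test of each group of miRNAs (the 2 brightest if none pass), and the 5 entries of highest level in each group of arrays. miR-214-3p, miR-1246, miR-1229-3p and miR-1228-5p were named after their values were seen. The 14 groups of miRNAs were fixed at the same time from general knowledge, and groups with at least 3 measured members were tested with limma's camera (preset correlation 0.01), with an estimated correlation and fry as alternatives, adjusted over the groups.

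Alternatives fixed beforehand were quantile normalization of all 4 arrays together, a 75th percentile taken over miRNAs above the median level, centring on the median, pseudocounts of 16 and 64, filters on dim probes, eBayes without the trend or with robust variance, a 2-fold threshold, the replicate number as a block, and leaving out each array. A normexp background correction with an offset of 50, followed by scaling to a common 75th percentile, was added after the data had been examined.

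The code was tested on simulated data with 1308 entries and 200 changed entries in 20 runs. For the comparison of treated with untreated arrays it recovered 100% of entries changed by 1.5-fold and 100% of those changed by 2-fold, with 3.7% of calls false. The simulated noise was taken from the differences between the deposited replicates, which normalization within groups appears to have shrunk. Changes under 1.5-fold were not simulated, so recovery of the smaller changes reported here is not known. When the simulated arrays were also quantile normalized within groups and scaled to a common 75th percentile, as the deposited values appear to be, 39.7% of calls were false. This separate run was made after the first simulation, which included the scaling, had shown too many false calls. Figures were drawn with matplotlib 3.10.9.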

Results

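Small RNA from exosomes, the small vesicles that cells release into their medium, was profiled on 4 microarrays of 1 colour (Cy5), each with a value for 1308 human miRNA entries. The vesicles came from Hep3B, a human hepatocellular carcinoma line, kept for 2 days in medium free of other exosomes. In 2 arrays the cells had received 10 µM camptothecin, an inhibitor of topoisomerase I that leads to DNA strand breaks. In the other 2 they had received no treatment per the labels, while the headers of the authors' ratios call the comparator DMSO. Which is right was left open. Deposited intensities, in arbitrary units, ran from 109 to 8436 on both treated arrays and from 91.4 to 12998 on both untreated arrays, and the 75th percentile was 250.15 on all 4. The number of arrays limits the precision. The labels do not say whether the 2 arrays of a group came from separate cultures, so the spread behind the p-values may be technical. It is also only the spread left after the arrays of each group were, by their values, quantile normalized together. If so, the p-values are too small. In simulated data with this normalization and the common 75th percentile imitated, 39.7% of calls were false at an adjusted p under 0.05.

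The comparison between treated and untreated cells asked which exosomal miRNAs change with an anticancer drug. Among miRNAs of at least median level, miR-1976 rose most, by 1.86-fold (log2 fold change 0.89 ± 0.049 SE, n = 2 arrays per group; limma with Benjamini-Hochberg adjustment, adjusted p = 0.00061). Next came miR-4728-3p, encoded in an intron of the receptor gene ERBB2, with 1.81-fold (0.85 ± 0.097 SE), and miR-877-3p, from a hairpin that is itself a spliced intron, with 1.74-fold (0.80 ± 0.052 SE). miR-4290 rose by 0.79 on the log2 scale and miR-483-3p, encoded in an intron of the growth factor gene IGF2, by 0.77. miR-197-3p rose from an intensity of 2331 to 3961, with the same value on both arrays of each group (0.77 ± 0.027 SE; limma adjusted p = 0.00021). The rest of the 12 highest were miR-6511a-3p, miR-3622a-3p, miR-6716-3p, miR-1260a, miR-4667-3p and miR-3662, with log2 fold changes from 0.76 down to 0.60.

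Among the decreases, miR-4497 fell 2.52-fold, from a mean intensity of 1677 ± 47.4 to 666 ± 31.9 (SD, n = 2; log2 fold change -1.33 ± 0.054 SE; limma adjusted p = 0.00027). miR-204-3p, the opposite arm of the better known miR-204-5p, fell 2.13-fold (-1.09 ± 0.050 SE), and miR-6126 fell 2.05-fold (-1.03 ± 0.051 SE). These 3 were the miRNAs past the test with a change of at least 2-fold, and 0 rose that far in the values as deposited. With all 4 arrays quantile normalized together, miR-1976 (log2 fold change 1.08) and miR-4728-3p (1.03) rose by over 2-fold, while miR-204-3p (-0.95) and miR-6126 (-0.90) stayed under it. miR-5787 fell by 0.95 on the log2 scale, miR-1273e by 0.86 and miR-1908, encoded in an intron of the desaturase gene FADS1, by 0.81. The rest of the 12 lowest were miR-4525, miR-3960, miR-762, miR-1237-5p, miR-6087 and miR-1234-5p, with log2 fold changes from -0.75 to -0.69.

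**Figure D1:**
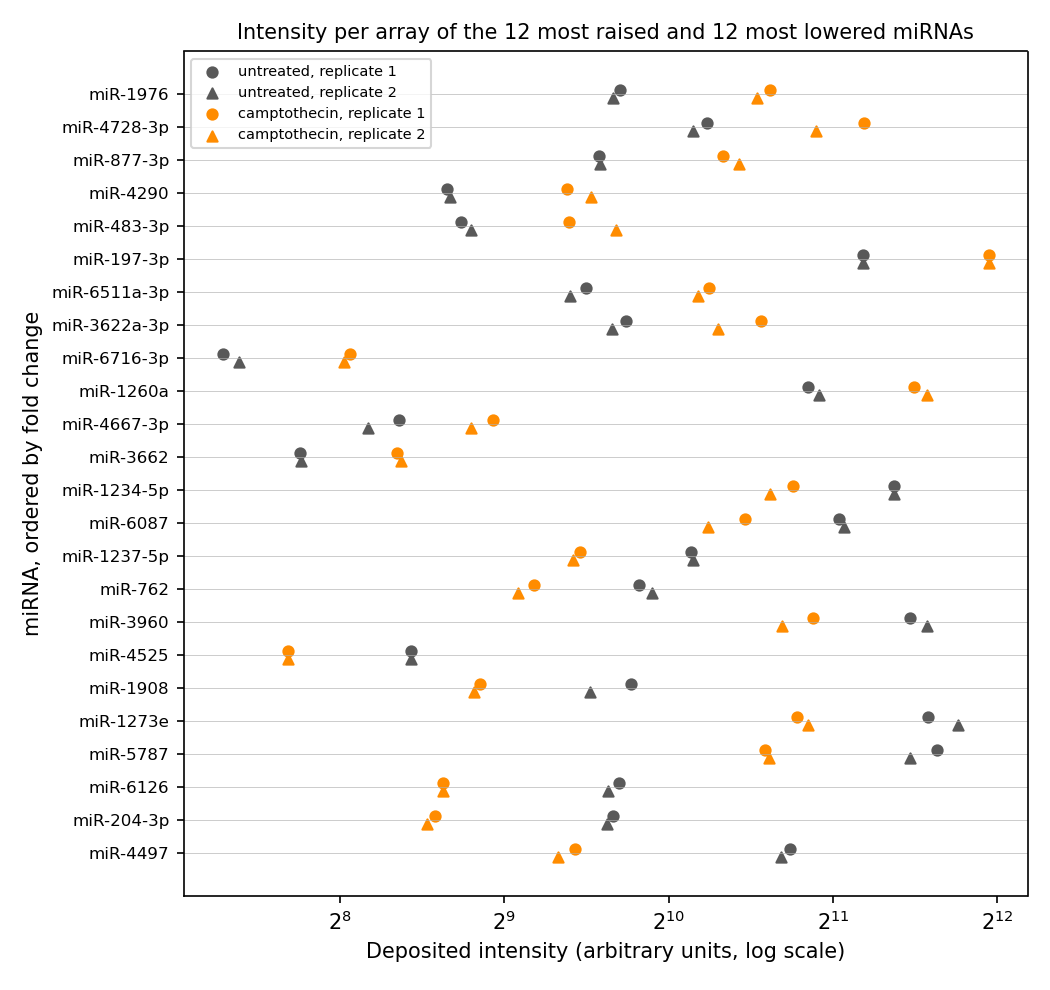
Deposited intensity (arbitrary units, log axis) of the 12 most raised and 12 most lowered miRNAs, with 1 point per array, circles for replicate 1, triangles for replicate 2, orange for camptothecin and grey for untreated. Both orange points lie on the same side of both grey points for all 24 miRNAs, as the rule that chose them required. This separation is therefore not further evidence of a change. It was also found for 78.67% of all entries. By chance it would be 33.3%, but only if all arrays had been scaled alike. Each group appears to have been normalized by itself, which can separate the groups without a change, so the 78.67% does not measure how many miRNAs changed. miR-4497 is the most lowered, at 666 against 1677.

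All 24 of these miRNAs kept their direction and stayed past the test when the 4 arrays were quantile normalized together, when each array was centred on its median, when the 75th percentile was taken over miRNAs above the median level, and after normexp background correction. Centring and the other 75th percentile shift all fold changes alike, so in these settings only small changes could turn sign. All these settings start from the deposited values. None gives back the spread between replicates that normalization within groups appears to have removed, so staying past the test is weak evidence. Under quantile normalization of all 4 arrays, miR-1976 had a log2 fold change of 1.08 ± 0.059 SE and miR-4497 one of -1.13 ± 0.060 SE (limma adjusted p = 0.0011 for both). With 1 array left out, 18 of the 24 passed without camptothecin replicate 1, 15 without camptothecin replicate 2, and 0 without either untreated array.

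The probes with the highest intensities belonged to a small set. miR-1273g-3p was the brightest entry on every array and was lower after treatment, at 8436 against 12998 (log2 fold change -0.62 ± 0.014 SE), though quantile normalization of all 4 arrays sets its fold change to 0 by construction. miR-4656 (-0.49), miR-1273a (-0.58) and miR-1273f (-0.64) fell as well. miR-766-3p rose by 0.39 on the log2 scale, from 3608 to 4716, and miR-4763-5p rose by 0.15. Apart from miR-1273g-3p, each passed the test with the same sign under quantile normalization of all 4 arrays. With each array centred on its median, miR-4763-5p was at 0.042 and did not pass (limma adjusted p = 0.386), nor did it with robust variance (limma adjusted p = 0.18).

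Across all 1308 entries, 606 passed the test, 459 of them higher and 147 lower after camptothecin (limma, Benjamini-Hochberg adjusted p under 0.05), and 743 had an unadjusted p under 0.05. The direction of this total depended on the scaling. The share of higher calls was 75.7% for the values as deposited, 53.3% with all 4 arrays quantile normalized together (90 higher, 79 lower), 35.8% with each array centred on its median (118 and 212), 91.5% with the 75th percentile taken over miRNAs above the median level (892 and 83) and 55.5% after normexp background correction (106 and 85). The median log2 fold change over all entries was 0.11 as deposited, -0.0093, 0.0067, 0.24 and 0.043 in the same order, so a small rise lies within the shift that the scaling alone makes. Of the 169 entries called after quantile normalization of all 4 arrays, 153 were also among the 606. The smallest p that an exact two-sided permutation test of 2 against 2 allows is 0.333. The total fell to 71 without camptothecin replicate 1, to 44 without camptothecin replicate 2 and to 1 without either untreated array.

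The calls were unevenly spread over signal level. In the dimmest 327 entries, 201 were called higher and 0 lower, with a median log2 fold change of 0.21. In the brightest 327, 61 were called higher and 129 lower, with a median of -0.12. With all 4 arrays quantile normalized together, the dimmest 327 held 3 higher and 1 lower call, and the brightest 327 held 61 and 54.

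**Figure D2:**
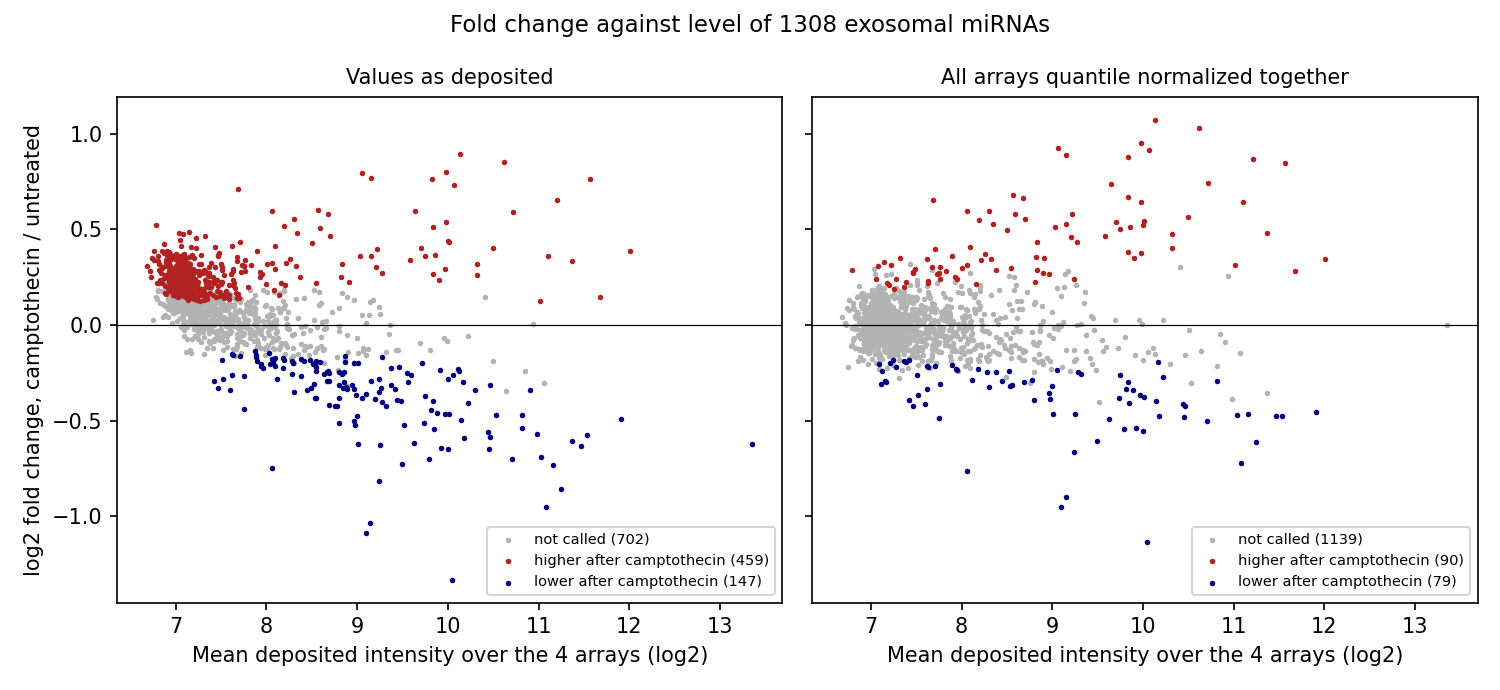
Log2 fold change, camptothecin over untreated, against mean deposited intensity over the 4 arrays (log2 axis) for 1308 miRNA entries, with red points higher, blue points lower and grey points not past the test. With the values as deposited (left) 459 are higher and 147 lower, with most red points at the dim end, and with all arrays quantile normalized together (right) 90 are higher and 79 lower.

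The miRNAs of liver and of the DNA damage response analysed here, 6 of 10 and 8 of 14 of those listed beforehand, were mostly dim. Their median levels were 146 and 133. The miRNAs with values in this paragraph lay from the 3.82 percentile of level (miR-122-5p) to the 47.2 percentile (miR-210). miR-122-5p, the most abundant miRNA of hepatocytes, read 137 ± 2.5 after treatment against 105 ± 1.8 without (SD, n = 2), a level at the 3.82 percentile of all entries, and was called higher (log2 fold change 0.39 ± 0.050 SE; limma adjusted p = 0.0062). With all 4 arrays quantile normalized together its log2 fold change was 0.17 and it did not pass (limma adjusted p = 0.102), while after normexp correction it was 0.41 and passed (limma adjusted p = 0.0281). miR-16-5p (0.34), miR-34a-5p (0.28), miR-192-5p (0.23) and miR-210 (0.16) were called higher as deposited and passed in neither of those settings. Their log2 fold changes shrank under quantile normalization, to 0.15, 0.099, 0.095 and 0.038 in that order. After normexp correction they stayed closer to those as deposited, at 0.37, 0.27, 0.21 and 0.11. miR-221-3p had a log2 fold change of 0.13 and did not pass (limma adjusted p = 0.055), and its sign turned under quantile normalization (-0.027). let-7a-5p and miR-21-5p were not analysed here.

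Of the 14 groups of miRNAs fixed beforehand, 12 had at least 3 measured members and were tested, with 104 different members, of which 71 lay below the median level. Among these 104, 46 were called higher and 4 lower as deposited, 6 and 3 with all 4 arrays quantile normalized together, and 8 and 3 after normexp correction. For comparison, of all entries as deposited, 201 of the dimmest 327 and 128 of the next 327 were called higher, and 0 lower in either. With limma's camera, which sets a group against all other entries, 0 of the 12 passed after Benjamini-Hochberg adjustment, 1 had an unadjusted p under 0.05, and 0 passed with an estimated correlation. With fry, which tests a group by itself, 9 passed as higher for the values as deposited, 7 after normexp correction, 0 with all 4 arrays quantile normalized together and 0 with each array centred on its median. Below, each group has its calls for the values as deposited, followed by those adjusted over the list alone and by those with all 4 arrays quantile normalized together (quantile).

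Of 11 measured miRNAs regulated by p53, a tumour suppressor that Hep3B cells lack, 9 were called higher and 0 lower (10 and 0 adjusted over the list alone; quantile 1 and 0). The largest changes were those of miR-34b-3p (0.41), miR-145-5p (0.36), miR-16-5p and miR-34a-5p, and miR-145-5p was the member that also passed under quantile normalization (0.22; limma adjusted p = 0.033). The group's mean lay 0.17 above that of other entries (camera adjusted p = 0.125 in limma; adjusted p = 0.676 with an estimated correlation). Of 8 DNA damage response miRNAs, 2 were called higher, miR-24-3p (0.26) and miR-138-5p (0.19), with 2 adjusted over the list alone and 0 under quantile normalization, where the group's mean turned to -0.017 against other entries.

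Of 6 liver-enriched miRNAs, 4 were called higher (5 adjusted over the list alone; quantile 0), namely miR-122-5p, miR-194-5p (0.27), miR-192-5p and miR-378a-3p (0.14). Of 9 miRNAs reported as raised in hepatocellular carcinoma, 3 were called higher (6 adjusted over the list alone; quantile 0), miR-222-3p (0.24), miR-93-5p (0.23) and miR-210. Of 13 reported as lowered in that cancer, 4 were called higher and 1 lower (4 and 1 adjusted over the list alone; quantile 2 and 0). The higher ones were miR-122-5p, miR-145-5p, miR-1 (0.33) and miR-29a-3p (0.25, which turned to -0.0017 under quantile normalization), and the lower one was miR-214-3p (-0.20). In the growth-promoting miR-17-92 cluster and its paralogs, 4 of 6 were called higher (4 adjusted over the list alone; quantile 0), miR-363-3p (0.26), miR-93-5p, miR-20b-5p (0.22) and miR-19b-3p (0.16). Both measured members of the epithelial miR-200 family, miR-200c-3p (0.28) and miR-200b-3p (0.20), were called higher (2 adjusted over the list alone; quantile 0). The let-7 family was not analysed here.

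Among 12 miRNAs often abundant in exosomes, 2 were called higher and 2 lower (1 and 1 adjusted over the list alone; quantile 1 and 1). miR-423-5p fell by 0.44 on the log2 scale, and by 0.34 under quantile normalization. miR-320b was lower (-0.21), and miR-16-5p and miR-150-5p (0.32) were higher. The signs differed for this group, with a median log2 fold change of 0.042, a mean of -0.061 against other entries, a downward direction in camera and an upward one in fry. Of 10 entries whose sequences overlap ribosomal, transfer or small nuclear RNA, 3 were called higher and 1 lower (3 and 1 adjusted over the list alone; quantile 3 and 2). miR-1260a and miR-1260b, which resemble transfer RNA, rose by 0.65 and 0.59, miR-663a fell by 0.34, and all 3 passed with the same sign under quantile normalization. miR-4485, which overlaps mitochondrial ribosomal RNA, was called higher as deposited (0.22) but did not pass under quantile normalization (0.031, limma adjusted p = 0.713).

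Among 3 miRNAs of blood cells, which can enter with serum, 1 was called higher, miR-150-5p (0 adjusted over the list alone; quantile 0). Of 8 miRNAs typical of muscle, nerve or fibroblasts, 5 were called higher and 1 lower (5 and 1 adjusted over the list alone; quantile 3 and 0). The muscle miRNAs miR-206 (0.46 ± 0.049 SE) and miR-1 rose, as did miR-145-5p of smooth muscle and fibroblasts, and these 3 passed under quantile normalization too. miR-133a had a log2 fold change of 0.21 as deposited and 0.034 under quantile normalization, where it did not pass. Of 11 members of the primate-specific miRNA cluster on chromosome 19, 3 were called higher (3 adjusted over the list alone; quantile 0), with miR-516b-5p at 0.22 and miR-520d-5p at 0.21, both of which turned sign under quantile normalization, and miR-518c-5p at 0.17. Of 29 members of the imprinted cluster on chromosome 14, 15 were called higher (15 adjusted over the list alone; quantile 0), led by miR-382-3p (0.45), miR-379-3p (0.32), miR-1185-1-3p (0.31) and miR-337-3p (0.31).

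The comparison of replicate arrays asked whether arrays of a group differed less than arrays of different groups. Across entries, which are not independent replicates, Pearson's r was 0.992 between the 2 treated arrays, 0.996 between the 2 untreated arrays and 0.974 to 0.976 between groups. The SD of log2 differences was 0.11 within the treated group, 0.084 within the untreated group and 0.234 to 0.242 between groups. By rank the groups were less distinct. Spearman's rho over all entries was 0.962 between the treated arrays, 0.979 between the untreated arrays and 0.936 to 0.961 between groups. The treated arrays were thus barely closer to each other than camptothecin replicate 2 was to untreated replicate 1. Among entries at or above the median level rho was 0.979, 0.991 and 0.944 to 0.951 in the same order. Within each group all 1308 sorted values were equal on both arrays, so part of the spread between replicates had been removed before deposit, and 38 entries in the treated group and 45 in the untreated group held identical values on both arrays. miR-197-3p, miR-1273g-3p and miR-4656 were identical in both groups, and their errors come from the spread that limma shares across entries.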

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

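Only the normexp correction was chosen after the data had been examined. The 24 most changed miRNAs (23 in the brightest 327 entries) kept their sign. By their selection, only quantile normalization, centring, the other 75th percentile and normexp could turn it. Calls were lost only with an array left out or a 2-fold threshold. The total of 606 calls (459 higher, 147 lower) became 169 (90 and 79) with all 4 arrays quantile normalized together, 975 (892 and 83) with the 75th percentile over miRNAs above the median level, 330 (118 and 212) with each array centred on its median and 191 (106 and 85) after normexp correction; the cause was not tested here beyond these scalings. With fewer entries tested it was 267 (125 and 142) among entries at or above the median level and 190 (61 and 129) among the brightest 327. Requiring a 2-fold change left 3 (0 and 3), with adjusted or unadjusted p. Pseudocounts of 16 and 64, no intensity trend and robust variance gave 604, 601, 611 and 629. Leaving out 1 array gave totals from 1 to 71, with 0 to 29 higher and 1 to 42 lower; the array left alone in its group is then assumed to vary like the other group, and the call left without either untreated array is miR-1273g-3p. With the replicate block the total was 550, of which 78.5% were higher, and of the named miRNAs miR-378a-3p, miR-19b-3p and miR-320b no longer passed. The deviations of same-numbered arrays from their group means correlated at -0.0717 across entries, so the numbers were not read as pairs.

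The count of groups of miRNAs past camera, 0, became 1 among the brightest 327 entries, where the entries that overlap other abundant RNAs, reduced to miR-1260a, miR-1260b and miR-1246, which by itself did not pass, had a limma camera adjusted p = 0.0306 (adjusted p = 0.388 with an estimated correlation), and 9 with fry. Under quantile normalization of all 4 arrays the sign turned for the DNA damage group (-0.01732), the chromosome 19 cluster (-0.04029), miR-221-3p (-0.0274), miR-29a-3p (-0.001715), miR-516b-5p (-0.01695) and miR-520d-5p (-0.0001192), none past the test there. The chromosome 19 cluster also turned among entries at or above the median level (-0.001738) and after normexp correction (-0.02898), and the blood cell group ranged from -0.02253, without camptothecin replicate 2, to 0.1397 when 1 array was left out. The cause of these changes of sign was not tested. Of the 65 named miRNAs called as deposited, 30 lost their call under quantile normalization of all 4 arrays, 23 with each array centred on its median and 26 after normexp correction. A lost call did not always mean a smaller change. After normexp correction miR-150-5p was at 0.38 and miR-337-3p at 0.32, against 0.32 and 0.31 as deposited, while miR-210 went from 0.16 to 0.11. The SD of log2 differences between replicates was 0.123 (treated) and 0.0742 (untreated) among entries at or above the median level. The other deposited table was not run because it holds the same values, nor was a filter on detected probes or a choice of the brightest probe, since no detection mark was used here and each name has 1 probe. Signal over background is unknown, which limits what dim probes such as miR-122-5p can show.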

Other observations

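All tests in this part, and the families and hairpins they concern, were chosen after the results had been seen.

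The miR-548 family, primate miRNAs derived from repeats, had 32 measured members, of which 15 were called higher and 0 lower as deposited (median log2 fold change 0.15). Its median level was 150. Of all entries, 201 of the dimmest 327 and 128 of the next 327 were called higher and 0 lower, so such a count is usual for dim probes. With all 4 arrays quantile normalized together 0 of the 32 passed and the median was 0.0066. The miR-320 family, whose best-known member matures without the enzyme Drosha, had 5 measured members, of which 0 were called higher and 1, miR-320b, was called lower, and 0 passed under quantile normalization.

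Most calls were higher, and of the 459 higher calls 201 lay in the dimmest 327 entries and 128 in the next 327. After normexp background correction the share of higher calls was 55.5%, against 75.7% as deposited, a fall that group scaling of signal that still holds background would give. Some dim miRNAs lost their calls there with changes about as large, such as miR-16-5p (0.34 to 0.37) and miR-337-3p (0.31 to 0.32). Others shrank, such as miR-210 (0.16 to 0.11). The share of calls by itself therefore cannot decide on this explanation. With all 4 arrays quantile normalized together the dimmest 327 entries held 3 higher calls. A general rise of scarce miRNAs in exosomes after camptothecin stays open, since no spiked-in RNA was used here to fix the scale.

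The 3p arms of mirtrons, hairpins that are themselves short spliced introns, were shifted up against their 5p arms in 11 of 11 hairpins. Those counted as mirtrons were miR-877 and hairpins numbered from miR-1224 to miR-1238. The mean shift was 0.60 ± 0.091 SE in log2 fold change. It was 0.085 ± 0.022 SE in 220 other hairpins with both arms measured, some of which may be mirtrons too. Of the 3p arms 9 were called higher (7 with all 4 arrays quantile normalized together), as for miR-877-3p (0.80) and miR-1229-3p (0.36), and of the 5p arms 5 were called lower (4), as for miR-1237-5p (-0.70) and miR-1228-5p (-0.59). The difference was 0.649 ± 0.065 SE after quantile normalization of all 4 arrays and 0.64 ± 0.068 SE once the trend of fold change on level was removed. In the 8 mirtrons with neither arm among the 24 most changed miRNAs it was 0.58 ± 0.058 SE and 0.56 ± 0.061 SE. These values argue against a difference in brightness between the arms, or a shift between groups that depends on level, as the whole cause. A single factor per group cancels in this difference, so scaling of that kind could not have made it. In those 8 the difference was 0.49 ± 0.097 SE as deposited (8 of 8 above 0), and a share of 8e-04 of 100000 random sets of 8 hairpins reached that mean. A mean of that size was thus rare among random sets of these hairpins. The share is a description and not a test, since mirtrons were picked after their values had been seen, those of miR-1228 and miR-1229 among the 8 included. The sets were matched in number and not on level, so they cannot exclude a shift shared by hairpins of similar brightness. Of the 220 other hairpins 129 were above 0, and some differed as much as mirtrons, such as miR-4728 (1.33) and miR-197 (1.01). The base composition of the arms, which differs in such introns and might change labelling or hybridization, was not tested, and neither was an effect of camptothecin on these introns, so both stay open.

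All 7 measured entries of the miR-1273 family, derived from repeats, were lower after camptothecin, with a median log2 fold change of -0.62. With all 4 arrays quantile normalized together, the 6 entries other than miR-1273g-3p had a mean of -0.42 ± 0.061 SE, against -0.58 ± 0.072 SE before, and 5 of the 6 passed, but the family was picked after 3 of these 6, miR-1273e (named for its decrease), miR-1273a and miR-1273f (named for their level), had been seen to be lower. The 3 entries that the rule for named miRNAs did not take had a median of -0.39 as deposited, at percentile 9.66 of 10000 random lists matched on level, so compression of bright signal on the treated arrays and a decrease of this family cannot be told apart. For miR-1273g-3p, the brightest entry of every array, compression cannot be told apart from a decrease either, since quantile normalization sets its fold change to 0 by construction. Signal shared between entries of similar sequence, which might make the 7 count as fewer, and an effect of camptothecin were not tested and stay open.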
